A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

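A pair of female gametophyte cell types of rice was compared on Affymetrix rice arrays, with 3 arrays of synergid cells and 3 of antipodal cells. The plants were greenhouse-grown Oryza sativa ssp. japonica of the cultivar Katy. Per the labels' protocols, the cells were dissected at anthesis without enzymes, synergids from the micropylar end and antipodals from the chalazal end of the embryo sac. RNA was purified on columns, amplified by a 2-cycle cDNA synthesis and labelled with biotin. The labelling protocol speaks of egg cells and zygotes in place of synergids and antipodals, so the number of cells behind each array is not given in the sources used here. Each array was assigned to its group from its title and its cell type label. The labels call the 3 arrays of a cell type biological replicates but do not name separate plants or days, so the p-values measure the spread between these samples, part of which may be technical.

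The authors deposited 1 table with a linear signal intensity per probe set and array. The submitters' processing notes name GCOS 2.0 and MAS5, the Affymetrix algorithm that summarises the probes of a probe set into 1 signal on each array separately. The trimmed mean of the deposited signal was 500.1 on every array, so each array had been scaled to a common level before deposit; no header or label records further normalisation. The table held 57381 probe sets, of which 123 were control probe sets and 57258 were not. All 6 of its columns were matched to a sample by name.

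Signal intensities were transformed to log2(signal + 16) with no further scaling between arrays. The 40% of probe sets with the lowest mean over all 6 arrays were left out, those with a mean below a signal of 36.7 (a log2 value of 5.72), along with the controls, which left 34355 tested probe sets. A fold change on this scale understates the change of dim probe sets. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on all 6 arrays with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets. The residual degrees of freedom were 4 and the prior added 10.6. Every log2 fold change is the synergid mean minus the antipodal mean. A call is an adjusted p under 0.05, and calls were also counted with an absolute log2 fold change of at least 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

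Genes were named from the platform annotation and updated through gene numbers in a RefSeq gene table of assembly ASM3414082v1. Of the 57258 probe sets, 22436 were paired with 1 gene, 95 with several and 34727 with none here. The 17905 genes with a probe set of their own all matched the RefSeq table, but only 2451 had a name other than a locus or clone number, and the tables used here carry no gene descriptions. No probe set with several genes was named. A gene with more than 1 probe set was represented by the one with the highest mean. No genome was used, so no coordinates are given.

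The naming rule took the 10 highest and 10 lowest log2 fold changes among represented genes with an informative name, an adjusted p under 0.05 and no overlap between the 3 synergid and the 3 antipodal arrays. For each gene list described, it took at most the 2 members with the highest positive and the 2 with the lowest negative log2 fold change among those past the threshold, or the member with the highest mean where none passed. Because few called genes had a name, 3 additions were made after the values were seen: the 10 highest and 10 lowest called genes known by locus only, named genes with the smallest p outside the threshold, and list members with the smallest p.

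Gene lists covered families, pathways and markers of other cell types. The 44 lists written before the data were examined were search patterns for gene names and descriptions; with no descriptions, 21 of them matched any gene and 236 genes in all. A second set of 41 lists on the same themes, written as symbol patterns, was added after the gene tables and control probe sets had been seen but before any gene was compared between groups; 40 of these matched, with 1227 genes. Lists with at least 5 tested genes were tested with camera at its preset correlation of 0.01 and at an estimated correlation, and lists with at least 2 were tested with fry, all on 1 probe set per gene (15936 genes). Members were also counted with p adjusted over the list alone. These p-values were not corrected across the lists, and a gene in several lists was counted in each. At least 1 member passed in this way in 6 of 21 fixed lists and 13 of 40 added lists.

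The test was checked on simulated data: 5 draws of 34355 probe sets with noise set from the average spread of these arrays, each with 200 changed by a known amount. It recovered 0% of probe sets changed 2-fold, 14% of those changed 4-fold, 44% of those changed 8-fold and 70.8% of those changed 16-fold, and 5.01% of its calls were false (17 of 339). The draws took noise as independent between probe sets and scattered the variances more widely than the fitted prior. These rates therefore need not hold for the real arrays. In 5 of 5 simulated draws a list shifted by a log2 value of 1 passed camera, and 0 of 175 other list tests did. The shifted list was the added cell cycle list of 69 tested genes, with every member moved and all genes drawn independently. In the real data members of a list can vary together (estimated correlation 0.438 for core histones). The check therefore gives neither the power nor the error rate for smaller or correlated lists. For arrays, the number of arrays limits the precision.

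The test, filter, pseudocount, naming rule, 44 lists and most alternatives were fixed before the data were examined. Those alternatives were pseudocounts of 1 and 64, no filter or a stricter one, quantile normalisation, median centring, other variance models, an unmoderated test, the replicate number as a block, array weights, leaving out probe sets that can cross-hybridise (suffixes _s_at and _x_at), and leaving out each array in turn. Alternatives that treat the number format of the table or the level of the poly-A spike-in controls as a batch were added after the data were seen.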

Results

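Synergids and antipodals are accessory cells of the embryo sac: the synergids flank the egg cell at the micropylar end, where the pollen tube enters, and the antipodals lie at the opposite, chalazal end. The data comprised 6 arrays of rice cells isolated at anthesis, 3 of synergids and 3 of antipodals, and the comparison asks which genes differ in transcript level between these cell types. Median signals of the non-control probe sets on the synergid arrays were 46.5, 67.1 and 63.4, and those on the antipodal arrays were 63.5, 170.3 and 54.4. Antipodal array 2, the one with a median of 170.3, also had the brightest hybridisation spike-in controls, 60392 against 6311 to 12463 on the other arrays (geometric mean of 27 probe sets). It also correlated least with the rest (Pearson r of 0.734 to 0.783 across tested probe sets). Over all 6 arrays the mean r was 0.862 within cell types (SD 0.0700, range 0.764 to 0.930, n = 6 pairs) and 0.843 between them (SD 0.0756, n = 9 pairs), a difference smaller than either SD. Without antipodal array 2 the means were 0.906 and 0.890. Synergid array 1 correlated at 0.923 with each of antipodal arrays 1 and 3, and at 0.889 and 0.930 with synergid arrays 2 and 3. Antipodal arrays 1 and 3 correlated at 0.904 with each other. The ratio of the 3′ to the 5′ actin control probe set lay between 77.9 and 689 on the 6 arrays, so probe sets far from the 3′ end report less signal on all of them. Antipodal array 2 had an actin ratio of 87.8 and a 3′ to 5′ GAPDH ratio of 57.3, against 89.6 to 236 for GAPDH on the other arrays. Its ratio of the 3′ to the middle probe set was 141 for GAPDH, against 8.30 to 17.5, and 20.6 for ubiquitin, against 2.29 to 3.30.

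**Figure D1:**
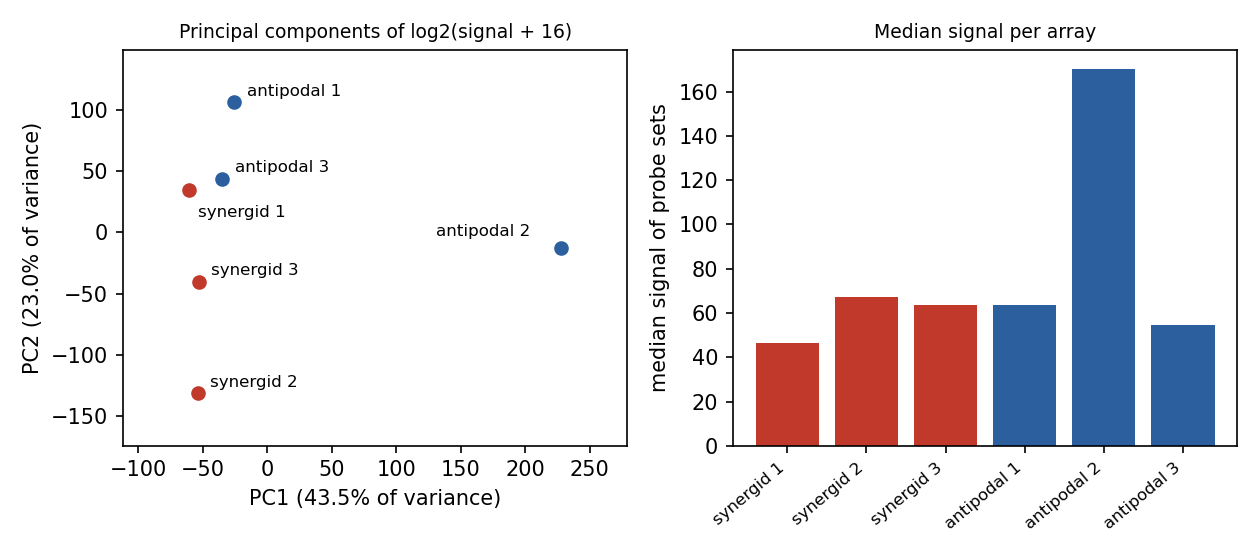
Left, the 6 arrays on the first and second principal components of log2(signal + 16) over the tested probe sets, with synergid arrays in red and antipodal arrays in blue (PC1 43.5% and PC2 23% of the variance). Right, bars give each array's median signal; antipodal array 2, at 170.3, stands apart in both panels.

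The clearest named difference was a lipid transfer protein gene, LTP-2 (LOC4331362), a member of a family of small secreted lipid-binding proteins. Its mean signal was 11030 ± 6083 in synergids and 90.4 ± 73.3 in antipodals (SD, n = 3 each), 112-fold higher in synergids (log2 fold change 6.81, SE 0.59, adjusted p = 1.87e-05). Its antipodal signals were low (85.4, 19.8 and 166 on arrays 1, 2 and 3), so the size of the fold rests partly on the pseudocount. The serine carboxypeptidase gene cbp3 (LOC4328060) was 26.2-fold higher, at 38357 ± 19136 against 1446 ± 616 (log2 fold change 4.71, SE 0.41, adjusted p = 2.08e-05). OsNAAT1 (LOC9267778), which encodes a nicotianamine aminotransferase of the iron-chelating phytosiderophore pathway, was 10.9-fold higher, at 811 ± 194 against 69.4 ± 50.1 (log2 fold change 3.45, SE 0.63, adjusted p = 0.0281). OC-VIII (LOC4333170), a cystatin that inhibits cysteine proteases, was 4.24-fold higher, at 3891 ± 867 against 909 ± 246 (log2 fold change 2.08, SE 0.36, adjusted p = 0.0195). No gene with an informative name was called lower in synergids. Another named gene, SAM2 (LOC4326996), an S-adenosylmethionine synthetase chosen after its values were seen, gave probe sets that disagree. The called one had a log2 fold change of 4.67 (adjusted p = 0.00747), and the brighter one that represents the gene had 1.38 (adjusted p = 0.182). LTP-2 and cbp3 stayed past the threshold in 22 of 23 other settings, all but the unmoderated test, and LTP-2 had a log2 fold change of 6.17 without antipodal array 2 and 6.11 with a pseudocount of 64. OsNAAT1 had a log2 fold change of 2.76 with a pseudocount of 64 and was not called with a pseudocount of 1 (adjusted p = 0.0597). It lost its call without any 1 of the synergid arrays (adjusted p = 0.0735, 0.281 and 0.138 without arrays 1, 2 and 3; range over all settings 0.00314 to 1.00). OC-VIII lost its call without synergid array 2 (0.188), without antipodal array 2 (0.0681) and with median centring (0.123; range over all settings 0.00573 to 0.636).

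Genes known here by locus number only and probe sets with no gene named here held most of the highest log2 fold changes. The top values, 8.48 and 8.26, belonged to LOC4349079 and LOC4335393, and the next 5, from 8.26 down to 8.04, to probe sets with no gene named here. Among genes LTP-2 came next (6.81). LOC4349079 had a mean signal of 34869 ± 12301 in synergids and 92.8 ± 64.1 in antipodals (log2 fold change 8.48, SE 0.47, adjusted p = 7.87e-07). LOC4335393 had 39640 ± 15013 and 141 ± 136 (8.26, SE 0.53, adjusted p = 1.78e-06). LOC4338802 reached 43050 ± 15503 in synergids against 692 ± 503, and LOC4337873 10228 ± 2551 against 115 ± 106, with log2 fold changes of 6.16 and 6.57. Further genes of this kind were LOC4342738 (5.99), LOC4339868 (5.97), LOC4338381 (5.94), LOC4343827 (5.45) and LOC4351459 (5.27). Their size and order rest on the pseudocount, since their mean antipodal signals were low, from 13.7 to 88.2. With a pseudocount of 64 they had 4.55, 5.32, 5.18, 4.33 and 4.05, and LOC4349079 and LOC4337873 had 7.83 and 5.97, while with a pseudocount of 1 LOC4342738, LOC4343827 and LOC4351459 had 7.38, 6.20 and 6.18. Of the 44 genes named in these results as called over all probe sets or over a list, SAM2 aside, a pseudocount of 64 moved the fold by over 1.5 times for 12. Without antipodal array 1 the log2 fold changes of LOC4338802 and LOC4337873 were 5.55 and 7.197, and without antipodal array 2 that of LOC4335393 was 8.94. LOC4350320 (4.94, adjusted p = 0.0334) was the tenth. Its log2 fold change was 6.42 without antipodal array 1, 3.58 without antipodal array 2 and 1.86 on the 3 arrays with low poly-A control signal. Its call was lost in 11 of 23 other settings, among them without synergid array 2 (adjusted p = 0.253), antipodal array 2 (0.09998) or antipodal array 3 (0.0833; range over all settings 1.39e-17 to 0.787).

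The lowest log2 fold change, -4.45, belonged to a probe set with no gene named here. Among genes called lower in synergids, LOC4327808 had a mean signal of 10394 ± 7354 in antipodals and 692 ± 803 in synergids (log2 fold change -4.27, SE 0.72, adjusted p = 0.0170). LOC4350821 had 1594 ± 1709 and 49.3 ± 32.3 (-4.08, SE 0.79, adjusted p = 0.0446). The other 8 genes with the lowest values were LOC4335460 (-3.001), LOC4332954 (-2.94), LOC4330367 (-2.86), LOC4325407 (-2.83), LOC4326149 (-2.78), LOC4349318 (-2.73), LOC4324117 (-2.66) and LOC4325147 (-2.66). All 10 kept their sign in every setting run. Their lack of overlap between arrays fixed this in advance, except under quantile normalisation and median centring. Each of the 10 lost its call in 8 to 13 of the other settings. LOC4327808, for one, was not called without synergid array 2 (adjusted p = 0.154) or antipodal array 2 (0.168; range over all settings 1.60e-10 to 0.787). Its log2 fold change was -5.22, -3.49 and -4.92 without synergid array 1, synergid array 3 and antipodal array 3. That of LOC4350821 was -3.18 and -4.96 without antipodal arrays 2 and 3 and -3.30 with a pseudocount of 64, and that of LOC4326149 -2.14 without antipodal array 1. Without synergid array 1, LOC4332954, LOC4330367, LOC4325407 and LOC4325147 had -3.63, -3.46, -3.50 and -3.38.

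Over the 34355 probe sets tested with limma, 110 were called, 88 higher and 22 lower in synergids, and all 110 differed at least 2-fold. An unadjusted p under 0.05 was reached by 2851 probe sets, where 1717.75 would be expected by chance. Log2 fold changes ran from 1.603 to 8.48 among the calls higher in synergids and from -4.45 to -2.08 among those lower. All 110 called probe sets had no overlap between the cell types' arrays, as did 13.4% of all tested probe sets, against the 10% that chance gives for 3 arrays against 3. Of the called probe sets, 65 were paired with 1 gene (52 higher and 13 lower, 64 distinct genes), 45 had no gene named here, and 22 carried a suffix for possible cross-hybridisation. Among the 44 genes named as called, LOC4351459, LOC4332954, OsEXLA2 and OsRR4 were read from probe sets with such a suffix. The median log2 fold change of tested probe sets was -0.08, and 0.05 and 0.07 after quantile normalisation and median centring, which gave 73 calls higher and 3 lower, and 77 higher and 2 lower. The number of calls depended on the model: the unmoderated test gave 0, and without an intensity trend there were 31 higher and 0 lower. Array weights gave 130 higher and 63 lower, and the replicate number as a block 149 and 144. It depended also on single arrays, above all for the lower side. Without synergid array 1 there were 96 calls higher and 221 lower, without synergid array 2 there were 41 and 1, and without synergid array 3 there were 59 and 2. Without antipodal arrays 1, 2 and 3 there were 123 and 10, 80 and 5, and 106 and 18. All 88 and 22 probe sets kept their sign in each of these 6 runs. That was fixed in advance, since without overlap between the cell types' arrays no left-out array can turn a sign.

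Technical groupings were seen among the arrays, and their tests were chosen after the data were seen. Synergid 1 and antipodal 1 were written in the table with at most 9 digits and the other arrays with 10. With this format as a block there were 284 calls, 137 higher and 147 lower, and within the 4 arrays of the longer format 458 calls, 239 higher and 219 lower. The shorter format held 1 array per cell type and allowed no test of its own. Poly-A spike-in controls had geometric mean signals of 3865, 41189 and 6738 on the synergid arrays and 7597, 134411 and 53145 on the antipodal arrays (12 probe sets at the 3′ end). With high against low poly-A signal as a block there were 235 calls, 113 higher and 122 lower. Of the synergids the 3 high arrays held only array 2, and of the antipodals the 3 low arrays held only array 1. A lone array must be assumed to vary like the pair it is set against, with 1 residual degree of freedom. Counts of calls within these subsets are therefore not read as results. Both subsets are among the other settings behind each gene's tally of lost calls and its range of adjusted p. All 110 called probe sets were called again with the format block, and all but 1 of them with the poly-A block. Of the 44 called genes the fold moved by over 1.5 times for 19 on the high and 17 on the low poly-A arrays.

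**Figure D2:**
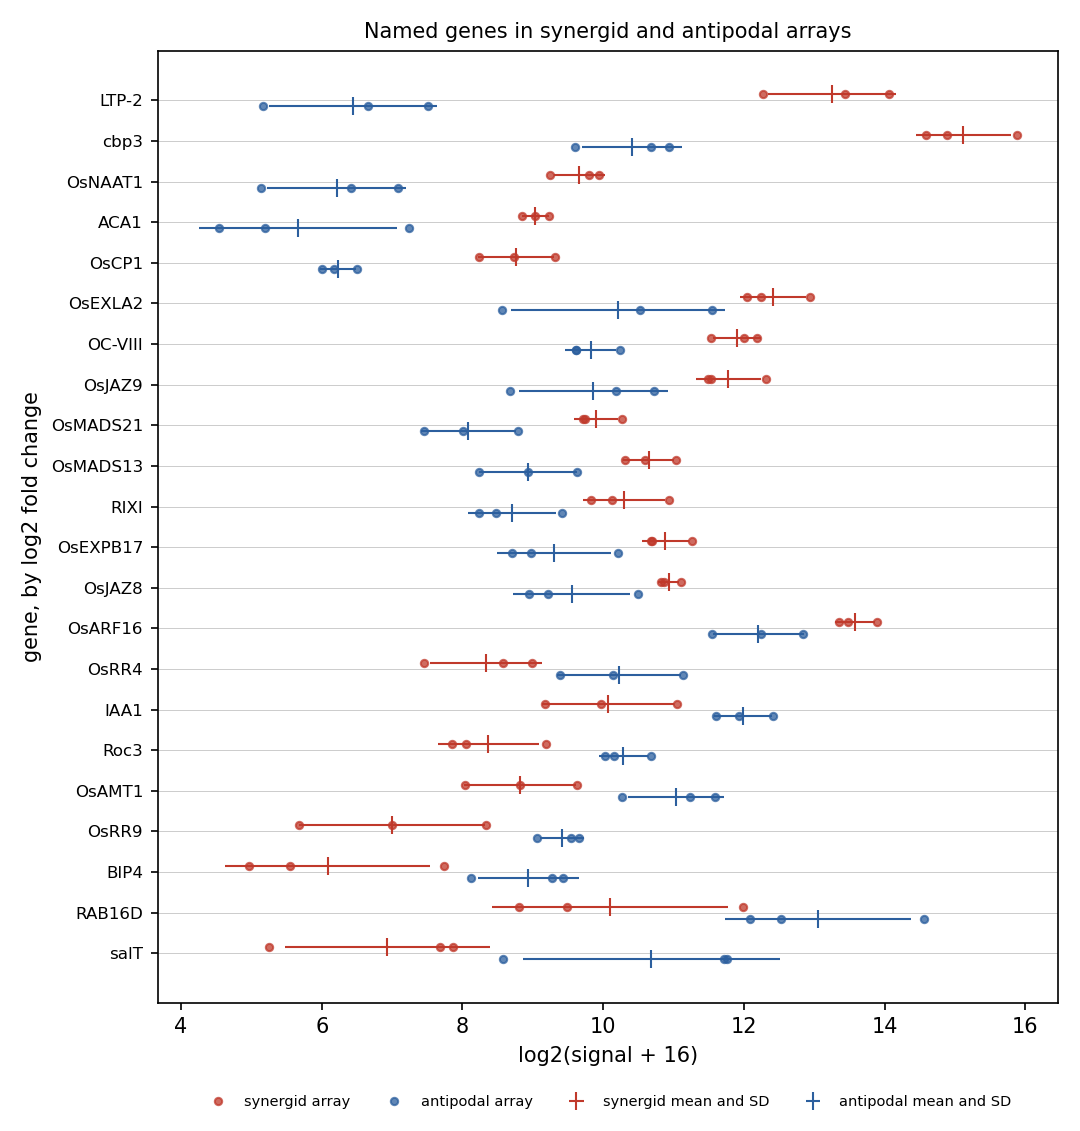
Points give log2(signal + 16) of each synergid array (red) and each antipodal array (blue) for 22 named genes, and bars the mean and SD of 3 arrays. LTP-2, cbp3, OsNAAT1 and OC-VIII passed over all tested probe sets, with log2 fold changes of 6.81, 4.71, 3.45 and 2.08, and the others only over their own gene list, from ACA1 at 3.38 to salT at -3.75.

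Several named genes fell just outside the threshold over all probe sets and are given as values chosen after they were seen. NIA1, a nitrate reductase gene, had a mean signal of 1165 ± 1248 in synergids and 6759 ± 1735 in antipodals (log2 fold change -3.18, adjusted p = 0.0595). MAP70.2, a microtubule-associated protein gene, had 4639 ± 370 and 1405 ± 632 (1.83, adjusted p = 0.0768). OsC3H1 had 2270 ± 1623 and 8302 ± 2630 (-2.04, adjusted p = 0.0784). OsBLE3, a brassinolide-enhanced gene, had 642 ± 708 and 3438 ± 1575 (-2.83, adjusted p = 0.0801).

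Among the lists of transcription factors, 3 MADS-box genes passed adjusted over the list alone, each higher in synergids. Of 24 tested MADS-box genes, 0 passed over all probe sets. OsMADS13 (1623 ± 421 in synergids against 510 ± 245, log2 fold change 1.72) and OsMADS21 (957 ± 224 against 276 ± 137, 1.82) belong to the ovule identity class, and both had an adjusted p of 0.0254 over the list. OsMADS29, expressed in nucellus and seed coat, had 5463 ± 2415 against 2213 ± 692 (1.25, adjusted p = 0.0448). The list as a whole had 13 members with a positive and 11 with a negative log2 fold change (camera adjusted p = 0.559). The same 3 genes made up, with ANT, the list of ovule sporophyte markers among those added on gene symbols, that is, markers of the tissue around the embryo sac. Adjusted over the 4 tested genes of that list in place of 24, the same p-values of the 3 MADS-box genes became 0.00424, 0.00424 and 0.00746. The shorter list alone lowers them, so this is no second support. ANT had a log2 fold change of 0.02. The symbol ANT is also used for a mitochondrial carrier, and the tables do not tell which gene is meant. The MADS-list calls of OsMADS13, OsMADS21 and OsMADS29 were lost in 9, 8 and 10 of 23 other settings. All 3 were lost with quantile normalisation (adjusted p = 0.0558, 0.0558 and 0.0696). They were lost also without synergid array 2 (0.0668, 0.0668 and 0.207), synergid array 3 (0.152 each) and antipodal array 1 (0.0669, 0.103 and 0.109). OsMADS13 and OsMADS29 were also lost without antipodal array 2 (0.0578 and 0.0636; range over all settings and the 3 genes 0.00335 to 0.594). In the ovule list OsMADS29 was lost without synergid array 2 (0.0554; range over all settings 0.00152 to 0.0695). Roc3, an epidermal homeobox gene, was lower in synergids over the added list of epidermis, meristem and vasculature (345 ± 195 against 1258 ± 321, -1.92, adjusted p = 0.0142), the only 1 of 13 members past the list's own threshold. Of 38 homeobox genes in the added list, 23 had a positive log2 fold change, and Roc3 alone passed over the list (adjusted p = 0.0414). That call was lost in 10 of 23 other settings, among them quantile normalisation (adjusted p = 0.0692), median centring (0.160) and leaving out synergid array 2 (0.125), synergid array 3 (0.214) or antipodal array 2 (0.101; range over all settings 0.0101 to 0.413). In the epidermis list it was lost in 6, among them median centring (0.0546) and without synergid arrays 2 and 3 (0.0713 and 0.0731; range over all settings 0.00413 to 0.185).

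Of the genes in the hormone lists none passed over all probe sets. In the list of ethylene, jasmonate and abscisic acid genes fixed in advance, 2 of 14 tested members passed adjusted over the list alone, both repressors of jasmonate signalling, and in the larger added list on that theme 0 of 55 did. OsJAZ9 had 3628 ± 1246 in synergids and 1072 ± 645 in antipodals (log2 fold change 1.92, adjusted p = 0.0169), and OsJAZ8 had 1943 ± 212 and 829 ± 524 (1.38, adjusted p = 0.0456). In the added list they had adjusted p values of 0.0664 and 0.0849. The call of OsJAZ9 was lost in 5 of 23 other settings, among them median centring (adjusted p = 0.0846), without synergid array 2 (0.118) and without antipodal array 2 (0.0620, log2 fold change 1.33; range over all settings 0.000408 to 0.202). That of OsJAZ8 was lost in 14, with each left-out array but antipodal array 3 (0.0589, 0.118 and 0.119 without synergid arrays 1, 2 and 3, and 0.175 and 0.108 without antipodal arrays 1 and 2; range over all settings 0.00417 to 0.334). The fixed list had 10 members above 0 and 4 below (camera adjusted p = 0.559; adjusted p = 0.807 with an estimated correlation). In the fixed auxin list, 1 of 32 members passed adjusted over the list alone, the Aux/IAA repressor gene IAA1 at LOC4323871 (1222 ± 799 and 4148 ± 1204, -1.92, adjusted p = 0.0220), as it did among the 42 of the added list (0.0289). The call over the fixed list was lost in 7 of 23 other settings, among them median centring (0.198) and without synergid array 2 (0.157), synergid array 3 (0.0749) or antipodal array 1 (0.0876; range over all settings 0.000584 to 0.342). Over the added list it was lost in 8, also without antipodal array 2 (0.0614; range over all settings 0.000766 to 0.337). Another locus that carries the name IAA1, LOC4334069, had 1.43 and did not pass. The median of the fixed list was -0.26 and turned to 0.08 with quantile normalisation. In the added cytokinin list, 2 of 27 members passed adjusted over the list alone, both at an adjusted p of 0.0488. They were the type-A response regulators OsRR9 (151 ± 140 and 678 ± 143, -2.42) and OsRR4 (338 ± 167 and 1335 ± 819, -1.88), whose calls were lost in 13 and 12 other settings. Without synergid arrays 2 and 3 and antipodal arrays 1 and 2 their adjusted p values were 0.172, 0.154, 0.133 and 0.105 for OsRR9 and 0.271, 0.154, 0.133 and 0.210 for OsRR4. OsRR9 was lost without antipodal array 3 too (0.0666; range over all settings and both genes 0.0102 to 0.652), and its log2 fold change was -3.08 without synergid array 1 and -1.76 without synergid array 3. The auxin response factor gene OsARF16, in the added list of AP2/ERF and B3 factors, had 12366 ± 2508 and 5026 ± 2163 (1.37, adjusted p = 0.0471 over the 29 genes of the list), and 0 of 9 passed in the fixed list on that theme. The call of OsARF16 was lost in 13 of 23 other settings, with each left-out array but antipodal array 1 (adjusted p = 0.0692, 0.306 and 0.138 without synergid arrays 1, 2 and 3, and 0.158 and 0.129 without antipodal arrays 2 and 3; range over all settings 0.00166 to 0.635). Its log2 fold change was 0.58 on the 3 arrays with low poly-A control signal.

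In the added list of cell wall loosening and remodelling, 3 of 33 tested members passed adjusted over the list alone, each higher in synergids at an adjusted p of 0.0332. The expansin-like gene OsEXLA2 had 5636 ± 1921 in synergids and 1601 ± 1315 in antipodals (log2 fold change 2.20). The beta-expansin gene OsEXPB17 had 1905 ± 469 and 688 ± 423 (1.58), and the endoglucanase gene OsGLU1 had 11964 ± 1994 and 4882 ± 3460 (1.49). The calls of OsEXLA2, OsEXPB17 and OsGLU1 were lost in 9, 11 and 11 other settings. All 3 were lost with quantile normalisation (0.0613 each), median centring (0.0971 each) and without synergid array 2 (0.0687 each), synergid array 3 (0.173, 0.224 and 0.173) or antipodal array 2 (0.162 each). OsEXPB17 and OsGLU1 were lost also without synergid array 1 (0.0543 each) and antipodal array 1 (0.0585 each; range over all settings and the 3 genes 0.000180 to 0.912). The log2 fold change of OsEXLA2 was 1.37 and 2.87 without antipodal arrays 2 and 3. The only tested gene of the fixed cell wall list, EXPA1, an alpha-expansin gene, had -1.65 and did not pass. The added list had 19 members above 0 and 14 below, and the added list of cellulose, callose and hemicellulose synthesis had 26 above and 15 below, with 0 of 41 past any threshold. In the added protease list, the cysteine protease gene OsCP1 was the 1 of 27 to pass (439 ± 172 and 59.6 ± 13.6, 2.54, adjusted p = 0.0287). Its call was lost in 8 of 23 other settings, among them without synergid arrays 1, 2 and 3 (adjusted p = 0.184, 0.296 and 0.0897) and antipodal array 3 (0.0807; range over all settings 0.0159 to 0.690). In the fixed defence list, the xylanase inhibitor gene RIXI was the 1 of 6 (1313 ± 561 and 430 ± 205, 1.59, adjusted p = 0.0255), while 0 of 20 passed in the added defence list (0.0833 for RIXI). Its call over the fixed list was lost in 9 of 23 other settings, among them quantile normalisation (0.0607) and without synergid array 2 (0.188), antipodal array 1 (0.0638) or antipodal array 3 (0.0760; range over all settings 0.00567 to 0.189). LTP-2 was the 1 of 5 tested lipid transfer protein genes to pass, and the median of the 5 was -0.05 and their mean 1.00. LTP110-A (1209 ± 213 and 948 ± 140, 0.34) and LTP (251 ± 97.5 and 662 ± 601, -1.05) did not pass.

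In the added list of water deficit and embryo maturation proteins, 2 of 13 members passed adjusted over the list alone, both lower in synergids at an adjusted p of 0.00586. They were salT, a salt-induced lectin gene (143 ± 106 in synergids, 2390 ± 1753 in antipodals, log2 fold change -3.75), and RAB16D, a dehydrin gene (1726 ± 2015 and 11428 ± 10987, -2.96). The call of salT was lost in 3 of 23 other settings, without an intensity trend (adjusted p = 0.0941), with the robust trend (0.0655) and in the unmoderated test (0.215; lowest over all settings 9.80e-05). That of RAB16D was lost in the same 3 (0.102, 0.153 and 0.240) and without synergid array 2 (0.0524; lowest over all settings 3.80e-08). The log2 fold change of salT was -2.91 and -4.81 without synergid array 2 and antipodal array 3, and that of RAB16D -3.91, -2.32 and -2.21 without synergid arrays 1 and 2 and antipodal array 1. OsAMT1, an ammonium transporter gene, was the 1 of 7 in the added list of amino acid, peptide and nitrogen transport (485 ± 267 and 2224 ± 935, -2.21, adjusted p = 0.00293), and its call held in 22 of 23 other settings. BIP4, a lumenal chaperone gene, passed only in the smallest of the lists that hold it, the fixed secretion list of 2 tested genes (81.0 ± 101 and 512 ± 219, -2.86, adjusted p = 0.00440). It did not pass among the 38 genes of the added secretion list (0.0836) or the 50 of the added heat shock and chaperone list (0.0550), and 0 of 22 passed in the fixed heat shock list. Its call in the fixed list was lost in 2 of 23 other settings, in the unmoderated test (0.0762) and on the 3 arrays with high poly-A control signal, which hold a lone synergid array (lowest over all settings 0.000610). Its log2 fold change was -3.68 without synergid array 1 and -2.12 with a pseudocount of 64. In the added list of aquaporins and ion transport, ACA1 was the 1 of 94 to pass (512 ± 71.9 and 54.5 ± 70.6, 3.38, adjusted p = 0.0420), higher in synergids, and 0 of 3 passed in the fixed list. That call was lost in 12 of 23 other settings, with each left-out array but antipodal array 1 (adjusted p = 0.0650, 0.0977 and 0.216 without synergid arrays 1, 2 and 3, and 0.0786 and 0.0799 without antipodal arrays 2 and 3; range over all settings 0.00415 to 0.783). The log2 fold change of ACA1 was 4.17 without antipodal array 1, 4.14 and 2.43 with pseudocounts of 1 and 64, and 1.79 on the 3 arrays with low poly-A control signal. Every list member named here as past its list's own threshold had no overlap between the arrays of the cell types, and except for LTP-2 none passed over all probe sets.

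As whole groups, no gene list passed. Of the 13 lists fixed in advance that had at least 5 tested genes, 0 passed camera (lowest adjusted p = 0.559; adjusted p = 0.807 with an estimated correlation). None of the 13 had an unadjusted p under 0.05, where 0.65 would be expected, and by fry 1 of 17 had an unadjusted p under 0.05 and 0 an adjusted one. Of the 36 added lists tested, 0 passed, and 7 had an unadjusted p under 0.05 where 1.8 would be expected (lowest adjusted p = 0.142). With an estimated correlation the lowest adjusted p was 0.678, which held for each of these 7, and 0 had an unadjusted p under 0.05. By fry 5 of 40 had an unadjusted p under 0.05 and 0 an adjusted one. These 7 leaned in both directions beside a median of 0.01 over all genes tested. With negative medians came protein secretion and ER folding (25 of 38 members below 0; BIP4 at -2.86 and CRT1, a calreticulin gene, at -1.01) and mitochondrial electron transport (9 of 11; OsAOX1A, an alternative oxidase gene, at -1.59). The same held for proteasome and ubiquitin conjugation (18 of 23), cytokinin (17 of 27) and cytosolic ribosomal proteins (16 of 23; RPS10-1 at -0.70). With positive medians came calcium signalling (47 of 74 above 0; CPK13, a calcium-dependent kinase gene, at 1.12) and receptor-like kinases (9 of 10; OsBRI1, the brassinosteroid receptor gene, at 0.85). With quantile normalisation none of the 7 medians changed sign, but the ribosomal proteins had 13 of 23 members below 0 and a median of -0.04. Median centring moved the median of all genes to 0.15, and secretion then had 21 of 38 members below 0 and the ribosomal proteins 12 of 23. Leaving out 1 array changed these calls: without antipodal array 2, secretion (adjusted p = 0.00738), mitochondrial electron transport (0.0219) and proteasome (0.0398) passed, and without synergid array 2, 6 lists passed. These were ribosomal proteins (0.0223), secretion, mitochondrial electron transport, proteasome and calcium signalling (0.0405 each) and heat shock proteins and chaperones (0.0408). With an estimated correlation 0 lists passed in either run (lowest adjusted p = 0.709 without synergid array 2 and adjusted p = 0.615 without antipodal array 2). Over the other settings run, the adjusted p reached 0.709 for secretion, mitochondrial electron transport, proteasome and calcium signalling, 0.816 for ribosomal proteins and 0.758 for heat shock proteins.

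Markers of other cell types were examined because dissected cells can carry RNA of their neighbours. The photosynthesis list had 9 members above 0 and 9 below (CAB2R, a light-harvesting protein gene, 5601 ± 2700 in synergids and 8524 ± 2842 in antipodals). Anther, tapetum and pollen markers had 3 tested genes, with OsINP1, a pollen aperture gene, at 206 ± 30.2 and 81.5 ± 54.2. Central cell and endosperm markers had 4 tested genes in the added list and 0 in the list fixed in advance; RAG2, a seed storage protein gene, had 588 ± 259 and 270 ± 206. None of these genes passed. The added list of epidermis, meristem and vasculature had 8 members above 0 and 5 below. In it Roc3, described above, passed over the list alone and was higher in antipodals. The fixed list of vascular and meristem markers had 4 above and 2 below, with 0 past the list's own threshold. The ovule sporophyte list, described above with the MADS-box genes, was the marker list with the highest median log2 fold change, 1.49 over 4 genes. No gene matched the egg cell list, so egg cell RNA was not examined.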

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

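The alternatives by number format and by poly-A signal were chosen after the data were seen. The gene lists by symbol were written after the gene tables and control probe sets were seen, but before any gene was compared between groups. Every count of calls at least 2-fold apart equalled the total of its setting. Among the planned settings, calls lower in synergids (22) became 8 with a pseudocount of 1, 42 without the filter, 6 with the stricter filter, 3 with quantile normalisation and 2 with median centring, and in these 5 settings the higher calls (88) ran from 73 to 96. Without an intensity trend there were 31 calls, 31 higher and 0 lower, and the unmoderated test gave 0 calls, 0 higher and 0 lower, 0 at least 2-fold, with 2147 unadjusted p under 0.05 against 1717.75 expected. The 110 calls thus rest on limma's moderation together with its intensity trend. Array weights gave 193 calls, 130 higher and 63 lower. The number format block gave 284 (137 higher, 147 lower), the 4 arrays of the longer format 458 (239 and 219), the poly-A block 235 (113 and 122), the 3 high poly-A arrays 213 (81 and 132) and the 3 low ones 78 (71 and 7). Leaving out 1 array at a time gave 42 to 317 calls, 41 to 123 higher and 1 to 221 lower. The cause of these shifts was not tested. Each subset of 3 high or 3 low poly-A arrays held a lone array of 1 cell type, which shows no replicate spread. The counts of calls from these subsets only record that the settings were run and cannot be compared with the others. All called probe sets kept their sign in every setting that tested them. Since their arrays do not overlap between the cell types, only quantile normalisation and median centring could have turned a sign. For the lists, 0 passed in any setting of those fixed in advance. Of the symbol lists, 6 passed without synergid array 2 and 3 without antipodal array 2, and with an estimated correlation 0 passed in either run. The similarity of the 6 arrays, as mean r within minus between cell types, was 0.0185, and 0.0178, 0.0105 and 0.0154 with quantile normalisation, no filter and no antipodal array 2. For single genes and their settings, 879 results kept their side of the threshold, 359 no longer passed and none turned sign. The arrays of these genes did not overlap either, so the kept signs carry no weight outside quantile normalisation and median centring. Of the 359, 25 and 21 fell on the high and low poly-A arrays, 2 of the 23 settings, where 1 residual degree of freedom was left. The replicate number as a block gave 293 calls, 149 higher and 144 lower. The same-numbered arrays' deviations from their group means correlated at 0.218, 0.116 and 0.0197, with 2 of 3 pairs over 0.1. Of the 6 arrays 5 correlated best with their own number, and synergid 3 with antipodal 2 (0.0215). Deviations within a cell type cancel out, so these 6 results depend on each other. They give at most a hint of a shared replicate effect. The main test did not take the numbers as pairs, and its balance of higher and lower calls depends on that choice. Low signal limits what can be seen: 12.8% to 29.8% of probe sets lay below a signal of 16 on each array. Apart from that, changes of 2-fold were not recovered in simulation, where recovery was not split by signal level.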

Other observations

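The tests on antipodal array 2, on scaling, on the batch of synergid 1 and antipodal 1 and on the ovule markers were chosen only after the result was seen. The tests of antipodal RNA in synergid array 1 were fixed before their values, although that array drew attention through the counts without it, and the second of them was added once the first was known. Genes of sugar metabolism, none past the threshold over all probe sets or over their list, went both ways. OsSUS1, a sucrose synthase gene, had a mean signal of 4337 ± 862 in synergids and 1586 ± 1466 in antipodals (SD, n = 3; log2 fold change 1.81, adjusted p = 0.260), and OsTPP1, a trehalose-6-phosphate phosphatase gene, had 21048 ± 8333 and 9226 ± 3537 (1.20). OsCIN7, a cell wall invertase gene, had 1291 ± 1125 and 3987 ± 1869 (-1.88, adjusted p = 0.264). OsSWEET11, a sucrose transporter gene, was bright in both at 20784 ± 4172 and 22508 ± 5425. Of 35 tested genes of the added sugar list 20 had a positive log2 fold change, and of the 8 of the fixed list 2 had.

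In the added list of aquaporins and ion transport, 47 of 94 members lay above 0 and 47 below. Its members OsCOPT1 and OsCOPT2, which encode copper transporters, had log2 fold changes of -2.26 (adjusted p = 0.264) and -2.15 (0.224), and osysl12, a metal chelate transporter gene, had -1.42 (0.224). Of the 3 tested ammonium transporter genes, AMT2-1 (-1.35) and AMT3-1 (-0.68) shared the sign of OsAMT1 without passing. In the added list of chromatin silencing and small RNA genes, 28 of 45 members had a positive log2 fold change; the argonaute genes OsAGO4b and OsAGO14 had 1.24 and 1.16, and fie, a Polycomb gene, had 15459 ± 2424 and 16434 ± 1494. Apart from OsAMT1, none of these passed a threshold. The naming rule took fie, OsSWEET11 and OsAMT1, and the other genes of sugar metabolism, transport and silencing given here were chosen after their values were seen.

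Antipodal array 2 stood apart from the other 5 arrays, with a median signal of 170.3. A synergid sample carrying the antipodal label is argued against: of the 80 probe sets called higher in synergids without this array, 79 (98.8%) were lower on it than on all 3 synergid arrays. Little labelled RNA on the array is consistent with its hybridisation controls, 4.85 times those of the next array, and stays open. Shorter or more degraded RNA on it stays open too, since 2 of 4 control ratios lay above those of every other array (GAPDH and ubiquitin, 3′ to middle, 141 and 20.6) while the 3′ to 5′ ratios of actin and GAPDH did not (87.8 and 57.3). An exchange with a sample outside this series and a biological difference of that sample stay open, untested.

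More probe sets were called higher than lower in synergids, 88 against 22. Scaling between arrays is argued against as the cause, since 96.1% of calls were higher with quantile normalisation (73 against 3). Antipodal RNA in synergid array 1 stays open: of the 221 probe sets called lower without that array 98.2% had at least 10% of the antipodal mean signal on it, but so had 51.6% on the mean of synergids 2 and 3, and probe sets picked without an array lie nearer the other group on it by selection alone. Over the 96 called higher it lay below the other synergids by a median log2 difference of -0.66 (quartiles -1.08 and -0.32). Its median share of the antipodal signal over the 221, 0.566, would bring -1.20 if all of it were carried over. Synergids 2 and 3 had a median share of 0.104 themselves, and selection raises the 0.566, so -1.20 overstates the shift to look for. The comparison therefore does not decide. A batch shared by synergid 1 and antipodal 1 and a true difference between the cell types stay open: with the batch as a block 48.2% of calls were higher because the lower calls rose from 22 to 147 and the higher ones from 88 to 137, and blocks by replicate number and by poly-A signal gave 50.9% and 48.1%, so this share does not single out that batch.

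The ovule MADS genes had higher means in synergids, and RNA of surrounding ovule tissue in the synergid samples is a candidate explanation. The tested ovule markers had a median log2 fold change of 1.49, but 3 of these 4 genes are the pattern itself, so the value does not separate carried-over RNA from expression in synergids, and the explanations cannot be told apart. ANT, the brightest of the 4, had 28375 ± 2861 in synergids and 28895 ± 8408 in antipodals. Its symbol may stand for a mitochondrial carrier, so its values weigh neither way. How many of these genes synergids express is not known from these data, and the cells were separated by dissection, with no sort.

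Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 110 calls, all at least 2-fold, and the highest other gave 0, so 1 of 10 splits gave as many. For the gene lists fixed in advance the real split gave 0 and the highest other 4. Any count reaches 0, so that 10 of 10 gave as many says nothing. Lists passed with synergid 1 grouped with synergid 2 and antipodal 1 (3) or with synergid 3 and antipodal 2 (3). They passed also with synergid 1 beside synergid 3 and antipodal 3 (4) or beside antipodals 2 and 3 (2). At its preset correlation camera thus passed lists also where the cell types were mixed. With 10 splits no share under 0.1 can be reached.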
